A study of Mus musculus with 8 samples.

How the data were processed

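H3K18la was measured by chromatin immunoprecipitation and sequencing in mouse T cells differentiated to Th17 cells and treated with vehicle or lactate. Groups and replicate numbers were taken from the labels: 8 samples in 4 groups of 2 biological replicates, of which the 4 anti-H3K18la libraries had a peak list. The labels call replicates biological without naming the animals or cultures behind them, so permutation p-values measure the spread between these libraries. Fisher's exact tests take genes or regions as units, and their p-values hold no spread between libraries.

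The authors called broad peaks for each library, and the peak lists were used as deposited. The submitters' processing notes name BWA 0.7.17, SAMtools 1.9 and MACS2 2.2.7.1 and the builds GRCm38 and mm10, with no role or order, and the peak files have the layout of MACS2 broad peaks. The control used for peak calling is not given in the sources used here. Each deposited list gives peak coordinates on mm10, a display score, the fold enrichment (a linear ratio), −log10 of the p-value and −log10 of the q-value per peak. The layout comes from the column order, since the deposited files have no header, and the score of each peak, by the authors' caller, equals the −log10 q multiplied by 10 and truncated. All of these are the authors' values for a peak within its own list, and they were used to describe, rank or filter peaks. The lowest −log10 q in the 4 lists was 1.03, 1.02, 1.00 and 1.02. Read depth is not given in the sources used here, so the precision of a single peak is unknown and no floor for undetected signal can be given.

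The authors' deposited table of gained genes and list of nearest genes hold identifiers alone. The list has 2181 Ensembl identifiers and the gained genes are 1583 entries for 1578 of them, and 2 gene identifiers of the table did not match the reference table. The design had foreseen an overlap test of the gained regions of that table; with no regions in it, the overlap was replaced by the nearest coding gene of each peak, chosen after the data were seen. For the same reason the rule naming 10 deposited regions was not used.

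Gene positions came from a RefSeq table for GRCm38.p6 with 49943 genes on assembled chromosomes, 21887 of them protein coding. The build is that of the peak files. The table has no strand, so transcription start sites could not be placed. The planned promoter window became a window of 1 kb on either side of both annotated ends of a gene, and a peak there need not lie at a promoter. All 361 members of the fixed lists (354 different genes) matched a gene.

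Peaks of the 4 lists were merged where they shared at least 1 bp. A region was gained with a peak in both lactate lists and neither vehicle list, lost in the reverse case, and shared with a peak in all 4. Group values are mean ± SD with an exact two-sided permutation test of the labels. Similarity is the Jaccard index in base pairs. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Gene lists were tested with Fisher's exact test, two-sided, at a false discovery rate of 0.05 (Benjamini-Hochberg over 15 lists). Background genes were all coding genes for gene-end peaks, and coding genes with a merged region in or within 1 kb of the gene for gained, lost and deposited genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

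The groups, tests, gene lists, rule for named genes and most other settings tried were fixed before the data were examined. The rule named the 10 gained and 10 lost regions with the highest −log10 q in the weaker of the 2 libraries, the 10 shared regions with the best mean rank of fold enrichment and the 10 longest. It also named Il17a, Il17f, Foxp3, Il2, Il2ra, Ldha, Slc16a1, Slc16a3 and Ep300, and up to 4 members per list in the gained, lost or deposited sets by −log10 q. A member with a gained region was ranked by that region and any other member by the strongest region in the gene, which puts members with a gained region lower. The rule asked for the vehicle values of lost members, Ikzf2 and Keap1, and the lactate values were used; either choice names Keap1 and not Ikzf2. One further gene named by the rule is not reported here. For a list with none it named the 2 members with the highest mean −log10 q. Regions off the assembled chromosomes and unnamed gene models were left out. Settings fixed in advance were −log10 q of at least 2 or 5, the same number of peaks in each list (the 30480 with the highest −log10 p), autosomes, merging of peaks up to 1 kb apart, peaks that cover 50% of a region, a window of 3 kb, shared regions matched on width, other backgrounds, each library left out and a replicate block.

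The steps were tested on simulated data. For gained, lost and shared regions, all of 10960 simulated regions were given their planted pattern of presence in the 4 lists (100%). These regions lay apart and their peaks overlapped, so this checks the code and not the merging of neighbouring peaks. For gene-end peaks in all 4 libraries, a list of 30 genes planted at 80% against 43.1% among 21887 genes was called in 91.5% of 200 runs. For gained genes, a list planted at 40% against 10.0% was called in 88.0% of runs. With nothing planted, 2% of runs of either kind called any list. Each coding gene was drawn independently, whatever its number of regions and also where it held none. The test of gained genes used genes with a merged region, whose number of regions differs, so these rates need not hold there.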

Results

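Lactylation of lysine 18 of histone H3 (H3K18la), a histone mark in which a lactyl group is added to the lysine, was mapped by chromatin immunoprecipitation and sequencing in mouse T cells. The cells had been purified from spleen and lymph nodes and cultured under conditions that give Th17 cells, the helper T cells that produce interleukin 17. They were then kept for 24 h with vehicle or with 25 mM sodium lactate. The series holds 8 samples: 2 biological replicates for each treatment with the antibody against H3K18la, and 2 for each treatment with control IgG. Peak lists of the 4 anti-H3K18la libraries were used, each called per library by the authors, so that n = 2 per treatment throughout. The IgG libraries had no peak list of their own in the sources used here. Read depth per library is not given in the sources used here, so a region without a peak is a region below the authors' threshold in that library, not a region without the mark. Treatments below are those of the labels, and a limit on the labels of replicate 2 is given with the authors' deposited table.

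The first question was whether H3K18la peaks were more numerous or covered more of the genome after lactate. The libraries labelled vehicle held 30480 and 45994 peaks, and those labelled lactate 47734 and 45388. The means were 38237 ± 10970 peaks for vehicle and 46561 ± 1659 for lactate (SD, n = 2), a difference of 8324 that lay within the spread between the vehicle replicates (exact permutation test, two-sided, p = 0.667; the smallest p possible with 2 against 2 libraries is 0.333). Peaks covered 36.7 and 63.0 Mb in the vehicle libraries and 69.4 and 62.7 Mb in the lactate libraries, or 49.8 ± 18.5 against 66.1 ± 4.72 Mb (SD, n = 2; exact p = 0.667). Protein-coding genes with a peak within 1 kb of an annotated end numbered 9726 and 10780 of 21887 in the vehicle libraries and 11314 and 11028 in the lactate libraries (exact permutation p = 0.333, the smallest possible). Vehicle replicate 1 had the shortest list, and without it the difference between the treatments was 567 peaks and 3.12 Mb. Without vehicle replicate 2 the difference was 16081 peaks and 29.3 Mb.

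**Figure D1:**
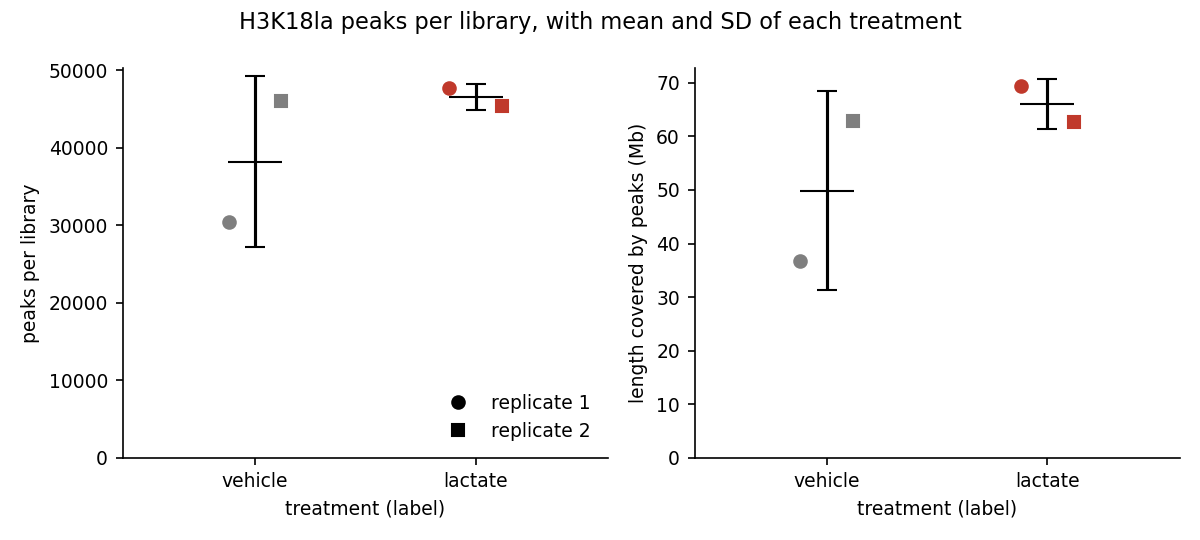
Number of H3K18la peaks (left) and length of genome covered by them in Mb (right) for each library, by treatment label; circles and squares are replicates 1 and 2, and bars give the mean and SD (n = 2). Vehicle replicate 1, with 30480 peaks and 36.7 Mb, lies below the other 3 libraries.

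Merging of overlapping peaks from the 4 lists gave 55999 regions, of which 19385 had a peak in every library and 21043 in 1 library only. The shared regions with the best mean rank of fold enrichment lay mostly at gene ends. The first was a region of 7.68 kb at Brd2, a bromodomain reader of acetylated histones, and H2-DMa, which loads peptides onto MHC class II (mm10, chromosome 17, 34117371 to 34125047; the authors' fold enrichment 10.5 and 11.7 in the vehicle lists and 9.61 and 11.4 in the lactate lists). It was followed by regions at Zfp869, Supt4a and Tspoap1, Efcab2, Gabarap (an autophagy protein) and Phf23, Dnajb12, Exoc2, and Msl1. Of the other 2, one lay inside Alpk2 and one 775 kb from Bcl11b, a transcription factor of the T cell lineage (chromosome 12, 107117392 to 107135567). The longest shared regions were led by 82.6 kb inside Bach2, a transcriptional repressor in lymphocytes (chromosome 4, 32349250 to 32431831), and 75.3 kb at Prkcq, the kinase PKC-theta of T cell receptor signalling (chromosome 2, 11155052 to 11230389). Next came 64.1 kb at Dad1, 62.7 kb at Enthd1 and Grap2 (the adaptor Gads), 55.5 kb inside Ets1, 53.2 kb inside Septin9, 50.6 kb inside Foxp1, 49.0 kb inside Myh9, 47.7 kb inside Clec16a and 46.9 kb at Lrig1.

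Most fixed gene lists, including T cell activation, central metabolism and translation, had H3K18la at gene ends in every library more often than other genes. Of all coding genes, 46.3% had a gene-end peak in no library. Expression was not measured here, so the lists were not set against genes of like expression. The cultures of all libraries held antibodies against CD3 and CD28, and IL-2. A gene-end peak in all 4 libraries was found for 9424 of 21887 coding genes (43.1%), and 11 of the 15 fixed gene lists departed from the remaining genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjustment over 15 lists). Among lists above the remaining genes were T cell receptor signalling and activation (29 of 30 genes, exact test, adjusted p = 6.26e-09), the tricarboxylic acid cycle and oxidative phosphorylation (31 of 34, adjusted p = 7.49e-08), the regulatory T cell programme (27 of 30, adjusted p = 6.82e-07) and ribosome and translation (24 of 26, adjusted p = 6.82e-07). IL-2 and STAT5 targets (22 of 24), histone acylation (24 of 27), redox genes (21 of 24), lipid metabolism (18 of 20) and glycolysis and lactate transport (22 of 28, exact test, adjusted p = 0.000288) were above as well. Markers of unrelated tissues (3 of 25, exact test, adjusted p = 0.00264) and of B cells (1 of 12, adjusted p = 0.0233) were below. The B cell call ended with a window of 3 kb (exact test, adjusted p = 0.0537) and at −log10 q of at least 5 (adjusted p = 0.757), where the redox call ended too (adjusted p = 0.208). Without vehicle replicate 1 the myeloid list was below (exact test, adjusted p = 0.0489). The Th17 list, with 13 of 30 genes, did not depart from the remaining genes (exact p = 1), and neither did the lists for Th1, Th2 and follicular helper cells (11 of 22), cytotoxic T cells (6 of 14) and myeloid cells (3 of 15). Among markers of unrelated tissues, Krt10 and Sftpc, a skin keratin and a lung surfactant protein, had a gene-end peak in all 4 libraries.

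**Figure D2:**
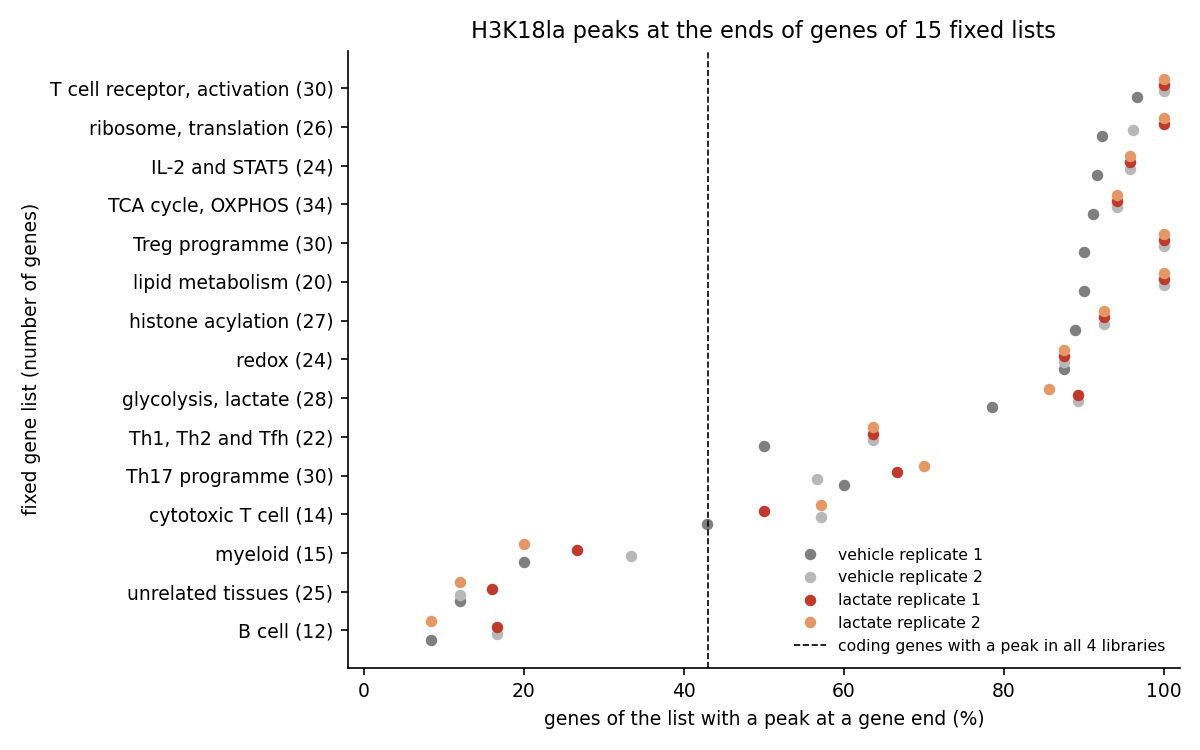
Share of the genes of each fixed list with a peak within 1 kb of an annotated gene end, in %, for each of the 4 libraries; the dashed line marks the 43.1% of coding genes with such a peak in all 4. T cell activation genes lie near the top in every library, and B cell genes and markers of unrelated tissues lie below the line.

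The main comparison asked which regions carried a peak after lactate and not after vehicle. A peak in both lactate libraries and in neither vehicle library was found at 2527 regions, called gained here, and the reverse at 99 regions, called lost. Without vehicle replicate 1, when a lost region needs a peak in 1 vehicle list while a gained region still needs both lactate lists, 3465 were gained and 6120 lost. The gained regions with the highest −log10 q in the weaker lactate library lay at the ends of Sestd1 (chromosome 2, 77279830 to 77280506; −log10 q 9.11 and 10.6), Ttc7b (7.72 and 6.69), Usp31 (6.22 and 9.0), Rab12, a small GTPase (5.72 and 6.69), and Emc2, part of a membrane protein insertion complex (9.49 and 5.44). The remaining named regions lay 5.71 kb from the histone gene H2ac12, 17.2 kb from Csf2ra (a receptor chain for GM-CSF), at the ends of the linker histone gene H1f0 with Gcat and of Zfp965, and inside Phip. The 10 named lost regions had −log10 q of at most 3.6 in either vehicle list. The first lay 16.9 kb from Pabpc1, encoding a poly(A)-binding protein (chromosome 15, 36578416 to 36578776; −log10 q 2.93 and 2.84), then inside Hipk2, Ranbp9 and Txndc16, at an end of Cnksr3, inside Insl6 and Celf2, 47.6 kb from Il9r (the interleukin 9 receptor), inside Rbms1 and 104 kb from Thbs1.

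The 4 libraries can be paired in 3 ways, and the count of gained regions was not the highest of the pairs. Peaks in vehicle replicate 2 and lactate replicate 1 alone were found at 2751 regions, and in vehicle replicate 2 and lactate replicate 2 alone at 2009. The mirror pairs, each holding vehicle replicate 1, had 280 regions with lactate replicate 2 and 387 with lactate replicate 1, against the 99 lost. Among regions at a gene end the gained count was the higher, at 303. Vehicle replicate 2 shared 216 such regions with lactate replicate 1 alone and 138 with lactate replicate 2 alone. With the same number of peaks in each list, 1013 regions were gained and 297 lost, beside 1116 and 885 for the other pairs that hold vehicle replicate 2. The order changed with stricter peaks: at −log10 q of at least 5, gained regions numbered 2204 against 395 and 333.

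**Figure D3:**
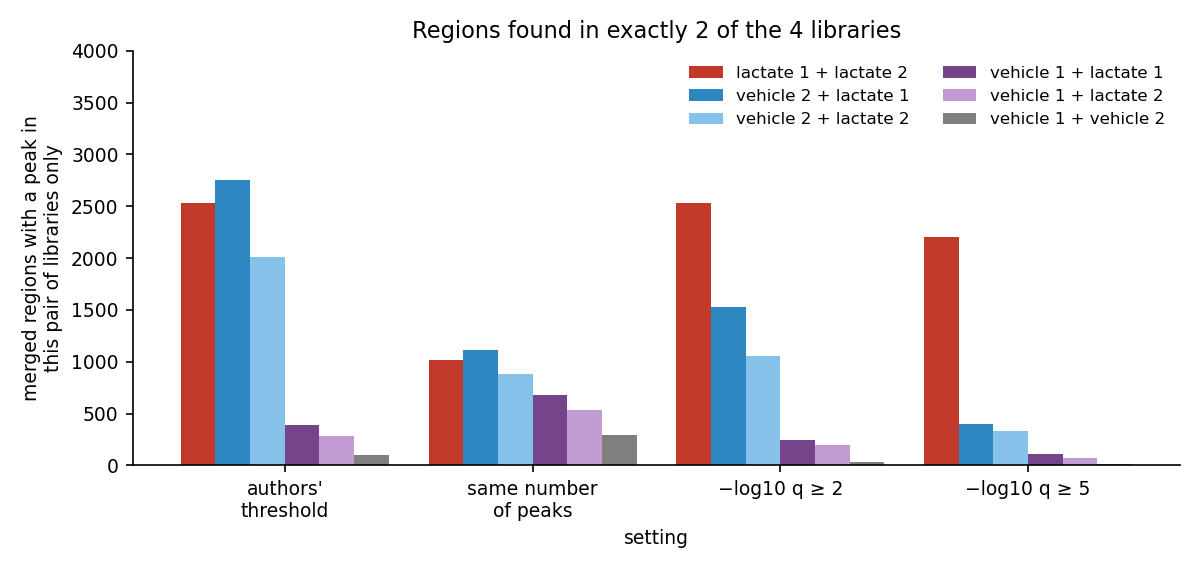
Number of merged regions with a peak in exactly 2 of the 4 libraries, for each pair of libraries and 4 settings of the peak lists. Gained regions (both lactate libraries) number 2527 against 2751 for vehicle 2 with lactate 1 at the authors' threshold, and 2204 against 395 at −log10 q of at least 5.

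Overlap between libraries was not higher within treatments at the authors' threshold. The Jaccard index in base pairs was 0.630 for the lactate libraries and 0.482 for the vehicle libraries. Across treatments it was 0.636 and 0.615 for the pairs with vehicle replicate 2 and 0.512 and 0.480 for those with vehicle replicate 1. The mean within treatments was 0.556 and across treatments 0.561, a difference of −0.00461 (exact permutation over the 3 pairings, p = 1; the smallest possible is 0.333). The difference was positive with −log10 q of at least 2 (0.00488) or at least 5 (0.0549), without vehicle replicate 1 (0.00468) and without vehicle replicate 2 (0.134).

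At the authors' threshold, gained and lost regions lay away from gene ends more often than shared regions did. Of the gained regions, 303 of 2527 (12.0%, exact 95% interval 10.7 to 13.3) overlapped a window of 1 kb around an end of a coding gene, against 8701 of 19385 shared regions (44.9%, 44.2 to 45.6; Fisher's exact test, two-sided, p = 1.55e-252). Of the lost regions, 9 of 99 (9.09%, 4.24 to 16.6) did so (exact p = 1.37e-14). Shared regions sampled to the same widths had shares of 48.2% and 46.5%. Regions are not replicates, so these tests describe the 4 libraries. Regions found in other pairs of libraries had shares of 6.87% to 8.93%. Among the 10000 highest peaks of each list, the gained share minus the shared share was −1.96 percentage points (Fisher's exact test, p = 0.448). At −log10 q of at least 5, the share among the 11 lost regions was 25.0 percentage points above the shared one (exact p = 0.111).

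Of 13108 coding genes with a merged region in the gene or within 1 kb of it, 1312 had a gained and 65 a lost region. Lists of T cell regulators contributed several: 7 of 30 regulatory T cell genes and 7 of 30 activation genes had a gained region (Fisher's exact test, p = 0.0258 each), but with adjustment over 15 lists the p-value was 0.193. The regulatory T cell genes were Satb1, Bach2, Foxo1, Foxo3, Foxp3, Itgae and Capg, and the activation genes Nfatc1, Nfatc2, Fyn, Cd5, Cd6, Nfkb1 and Ptprc. Both sets are complete, and the genes other than Foxp3 were chosen after their values were seen. Some of these regions were weak: the weakest in Bach2 had −log10 q 1.40 and 1.15 in lactate 1 and 2, and in Satb1 1.38 and 1.30. Itgae (4.77 and 2.30) and Fyn (3.41 and 3.47) held stronger ones. Bach2 also held the longest shared region, of 82.6 kb. No list passed the adjusted threshold for gained regions in Fisher's exact test, where 2 lists had an unadjusted p under 0.05, and none passed for lost regions, where 0 lists had one. Against random lists matched on merged regions per gene, a comparison chosen after the data were seen, 0 lists passed for either set. For gained regions the matched expectation was 8.18 regulatory T cell genes and 6.68 activation genes, beside the 7 found in each list. No matched lists were drawn for the settings that follow, so their calls do not allow for the number of regions per gene. For gained regions the regulatory T cell list passed without vehicle replicate 2 (exact test, adjusted p = 0.000524) and without lactate replicate 1 (9.46e-05), in the latter with the Th17 list and that for Th1, Th2 and follicular helper cells (0.0215 each). With all coding genes as background, the regulatory T cell and activation lists passed (exact test, adjusted p = 0.0123 each). For lost regions the regulatory T cell list (exact test, adjusted p = 4.69e-05) and that for Th1, Th2 and follicular helper cells (0.00676) passed without vehicle replicate 1, and the Th17 list (0.0145) without vehicle replicate 2. In the Th17 list, 4 of 25 genes had a gained region, against 10.0% of other genes (Fisher's exact test, p = 0.308). They were Rora, Rbpj, Runx1 and Sox5, chosen after their values were seen. The matched expectation for the Th17 list was higher, at 5.96 genes. In the Th1, Th2 and follicular helper list, 4 of 18 genes had a gained region: Stat4 (1 region), Il12rb2 (3), Il18r1 (1) and the Th2 regulator Gata3 (1). For that list the matched expectation was 3.98 genes, and 9.99% of other genes had a gained region (Fisher's exact test, p = 0.0983). In metabolism, gained regions lay in the glycolytic genes Pfkp and Pkm (1 each) and in Fdft1 of sterol synthesis. Mdh1 and Sdhb, members of the list for the tricarboxylic acid cycle and oxidative phosphorylation, held gained regions too. The lipid list had 4 of 20 genes with a gained region, Fdft1 beside Acaca, Scd2 and Acsl4, which were chosen after their values were seen. Its matched expectation was 2.95 genes (against other genes, Fisher's exact test, p = 0.133). The histone deacetylase gene Hdac4 had 4 and the deacylase gene Sirt2 1. Jak1, Rps19 and Itgam had 1 each. Keap1, a sensor of oxidative stress, had a lost region (chromosome 9, 21235533 to 21236374; −log10 q 1.62 and 2.92). So did 1 of 30 regulatory T cell genes, Ikzf2 (chromosome 1, 69548369 to 69549026, with −log10 q 2.61 and 1.12), chosen after its values were seen. Rps2, chosen after its values were seen, was the list gene with a gene-end peak in both lactate libraries and in neither vehicle library.

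Single loci named in advance differed in how much of them was marked, which does not extend to their programmes. Of the 30 Th17 list genes, 13 had a gene-end peak in every library and 7 in none. Il2ra, the IL-2 receptor alpha chain, overlapped 4 shared regions, and peaks covered 17.1 and 21.0 kb of the gene with 1 kb on either side in the vehicle libraries and 21.2 and 21.0 kb in the lactate libraries. Il17a had no peak within 1 kb of its ends in any library, and Il17f had one in vehicle replicate 1 and in both lactate libraries. Foxp3, the transcription factor of regulatory T cells, had 3 shared regions and a gained region inside the gene (chromosome X, 7592594 to 7593720; −log10 q 2.63 and 3.46 in the lactate libraries). Inside it also lay a region of vehicle replicate 1 alone (−log10 q 3.15) and one of lactate replicate 1 alone (1.26). The shared regions of Foxp3 had −log10 q from 1.42 to 4.70. In a window of 30 kb around Foxp3, peaks covered 10.2 and 12.3 kb in the vehicle libraries and 16.6 and 12.1 kb in the lactate libraries. That window is wider than the gene with 1 kb on either side, as used for Il2ra. It takes in part of a stronger shared region outside Foxp3 (−log10 q 5.83 and 7.32 for vehicle, 10.2 and 10.1 for lactate). The gene for the cytokine IL-2 had a weak shared region (−log10 q 1.89, 3.03, 2.66 and 3.0 in vehicle 1 and 2 and lactate 1 and 2). Ldha (lactate dehydrogenase), the lactate transporter genes Slc16a1 and Slc16a3, and the acetyltransferase gene Ep300 each had shared regions, with the highest −log10 q per library between 6.0 and 22.1.

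**Figure D4:**
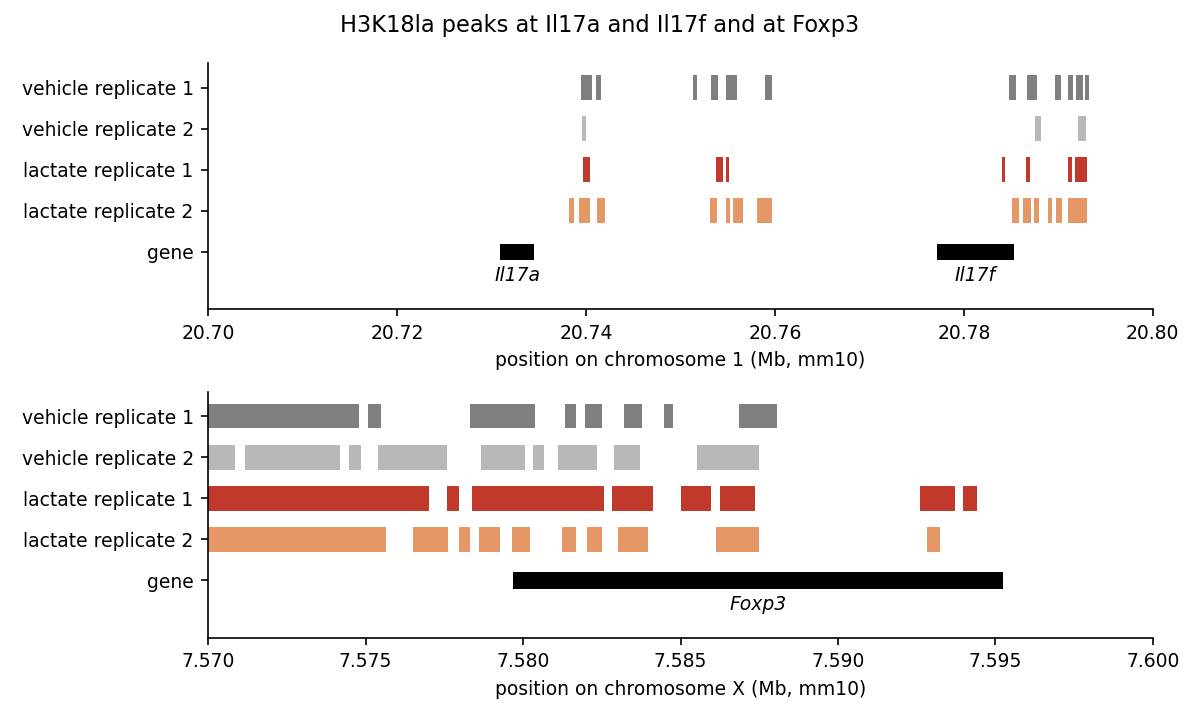
Peaks of each library (boxes, to scale) at Il17a and Il17f on chromosome 1 and at Foxp3 on chromosome X, by position in Mb (mm10), with gene extents in black. Between Il17a and Il17f, vehicle replicate 2 shows the fewest peaks, and the rightmost peaks inside Foxp3 are those of the lactate libraries.

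The authors' deposited table of gained genes was then set beside the peak lists. The table holds gene identifiers without regions, and 1581 gene identifiers matched the reference table, 1284 of them protein coding. T cell activation genes were the list that passed in it: 9 of 30 genes with a merged region, against 9.47% of other genes (Fisher's exact test, odds ratio 4.1, p = 0.00140, adjusted p = 0.0210). Its members include the immediate early factor Egr1, the NF-κB subunit Rel, the T cell receptor component Cd3d and the co-receptor Cd4, none with a gained region, and Nfatc1, Nfatc2 and Fyn, each with gained regions and chosen after their values were seen. Against random lists matched on merged regions per gene, the adjusted p was 1. The Th17 list had 7 of 25 genes in the authors' deposited table (adjusted p = 0.0539), among them Il6ra, Irf4, Stat3 and Prdm1, which hold no gained region. Runx1 and Rbpj, which hold gained regions, and Csf2 were the others, chosen after their values were seen. The regulatory T cell list had 7 of 30 (exact test, adjusted p = 0.0841), with Il2ra, Ikzf4, Nr4a3 and Nt5e, none of which holds a gained region, beside Bach2, Itgae and Gpr83, chosen after their values were seen, and the myeloid list 3 of 7 with a merged region (adjusted p = 0.0841). Named members of other lists in the authors' deposited table included Stat4 and Il12rb2 (Th1, Th2 and follicular helper cells), Bcl2 and Jak1 (IL-2 and STAT5). Further ones were Pfkfb4, Pfkp and Ldhb (glycolysis and lactate), Pdha1 (pyruvate dehydrogenase), Slc3a2 and Gsr (redox), Elovl6, Cpt1a and Acadm (lipids), Kat6a and Hdac4 (histone acylation) and Rps14. Markers of other cells in it were Fasl, Klrd1, Cd74, Cd68, Cd14, Itgam and Cebpe.

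Genes in the authors' deposited table were mostly those nearest to peaks found in vehicle replicate 2 and lactate replicate 1 alone, and less often those nearest to lactate-only peaks. Of the 1284 coding genes, 1204 (93.8%, exact 95% interval 92.3 to 95.0) were the nearest coding gene to a peak of that pair, against 8.94% of 11861 other coding genes with a merged region (odds ratio 153). Lactate-only peaks accounted for 446 genes (34.7%, 32.1 to 37.4) and peaks of the replicate 2 libraries alone for 438 (34.1%). Each remaining pair accounted for 3.82% to 8.80%. In the other direction, 51.7% of the 2327 coding genes nearest to peaks of vehicle replicate 2 and lactate replicate 1 alone were in the authors' deposited table, and 19.6% of the 2270 nearest to lactate-only peaks. Every direction given here for replicate 2, and for gained and lost regions, holds for the libraries as labelled.

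**Figure D5:**
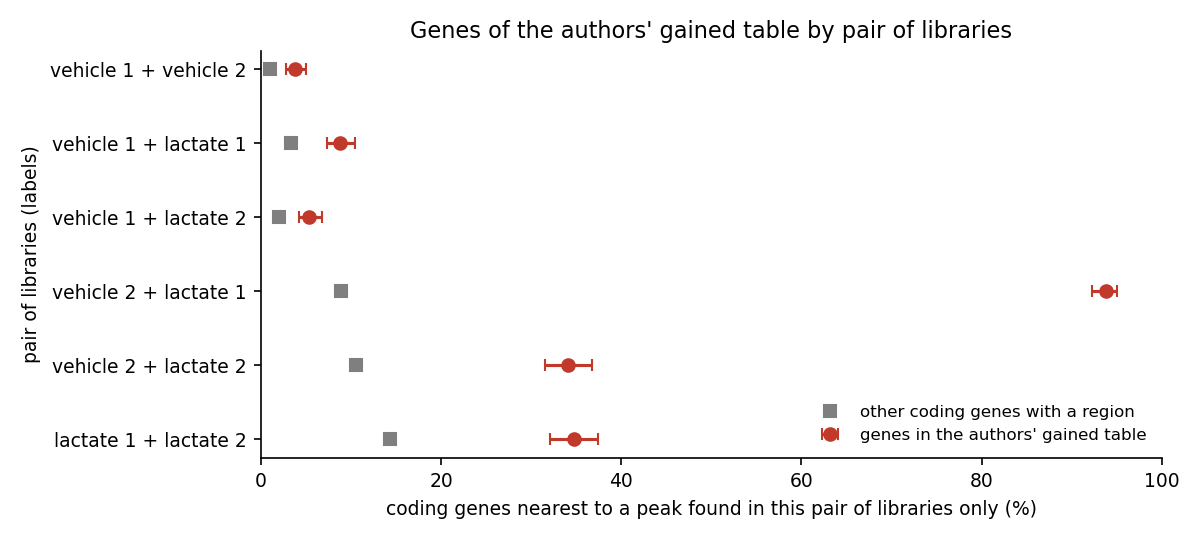
Share of coding genes, in %, that are nearest to a peak found in exactly the named pair of libraries: genes of the authors' deposited table (circles, with exact 95% intervals) and other coding genes with a merged region (squares). The pair of vehicle 2 and lactate 1 reaches 93.8%, against 34.7% for the lactate pair.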

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

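The alternatives that rank peaks by fold, keep the 10000 highest peaks, match random lists on regions per gene or change the nearest-gene rule were chosen after the data were seen. Across the alternatives, 110 values kept their direction and their side of the threshold, or stayed within 1.5 times, while 31 moved further, 10 changed sign or order and 1 no longer passed its test. The values that stayed include those of the replicate block that equal the main values by definition. Gained regions over the highest other pair turned from 0.919 to 1.66 at −log10 q of at least 2, where 31 regions were lost and within minus across similarity was 0.00488. At −log10 q of at least 5 these values were 5.58, 11 and 0.0549, with 5189 shared regions and a lost gene-end share 25.0 percentage points above the shared one (p = 0.111, Fisher's exact test). With the same number of peaks, 1013 regions were gained and 297 lost (1044 and 378 when ranked by fold). The 10000 highest peaks gave 401 gained, 220 lost and 5743 shared regions, a ratio of 1.01, and a gained gene-end share at −1.96 percentage points (exact p = 0.448). Merging peaks up to 1 kb apart gave 1614 gained and 52 lost regions and a ratio of 1.00, and asking for 50% coverage gave 9835 shared regions and a ratio of 1.01. The cause of these changes was not tested here. Ranking every list member by the strongest region in the gene, a setting chosen after the data were seen, kept 33 of the 45 named members.

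Leaving out a library in turn leaves its treatment with 1 list, so that gained and lost calls no longer ask for the same number of peaks. This gave 3465 to 12473 gained regions (3465 without vehicle 1, 9201 without vehicle 2, 8841 without lactate 1, 12473 without lactate 2) and 403 to 6120 lost regions, the highest without vehicle 1. Lost regions were 715 without vehicle 2, 534 without lactate 1 and 403 without lactate 2. Similarity within minus across treatments ran from −0.0919 without lactate 1 to 0.134 without vehicle 2, list calls for gained genes from 0 to 3 (3 without lactate 1), and for lost genes from 0 to 2 (2 without vehicle 1). With all coding genes as background, 2 lists passed for gained genes and 4 for the authors' deposited genes, where matched random lists left 0. Over regions, the deviations of same-numbered libraries as labelled had a correlation of 0.0383, which cannot settle whether the replicate number pairs the libraries. In the replicate block, pair 1 gained 20564 and lost 1175 regions and pair 2 gained 8936 and lost 9200, with 2527 and 99 in both pairs. Peaks differed by 8324 and covered length by 16.2 Mb (exact sign-flip p = 1 for both, smallest possible 0.5). The counts in both pairs and these differences equal the main values by definition, so they test nothing. Planned overlap settings for the deposited gained regions were not run, since that table holds genes, and start-site windows became gene-end windows. A fixed number of peaks gives no value for the number of peaks. Of the 10 named gained regions, 5 stayed in both lactate lists at −log10 q of at least 5, and of the 10 lost regions 0 stayed in both vehicle lists. No named lost region could stay, since their −log10 q was at most 3.6. Both counts restate the values by which the regions were named.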

Other observations

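The similarity of the splits and the counts with the same number of peaks were planned; their use to weigh explanations, and the other tests of this part, were chosen after the results were seen. Several effector genes of the Th17 list had a gene-end peak in the library labelled vehicle replicate 1 and not in that labelled vehicle replicate 2. They were Il17f, Ccl20 (a chemokine) and Ccr6 (its receptor), Il23r (the interleukin 23 receptor) and Il24. That is 5 of 30 list genes against 0.988% of other coding genes (Fisher's exact test, p = 1.16e-05, adjusted p = 0.00209 over the 180 tests of 15 lists and 12 ordered pairs of libraries). The reverse held for 4 of 30 list genes, Sox5, Prdm1, Csf2 and Hif1a, against 5.82% of other genes (exact p = 0.0944, adjusted p = 1), so list members went both ways. Each of these tests sets 1 library against 1 other with genes as the units, so the p-values hold no spread between libraries and say nothing about cultures in general. Lactate replicate 2 against vehicle replicate 2 also gave 5 of 30 (exact p = 0.000875, adjusted p = 0.0788). In a window of 100 kb around Il17a and Il17f, vehicle replicates 1 and 2 had 12 and 3 peaks and lactate replicates 1 and 2 had 7 and 13, covering 9.12, 1.86, 4.28 and 11.6 kb. A region beside Il17a was marked in all 4 libraries (20739243 to 20740677; −log10 q 2.76, 1.10, 2.55 and 4.00). Csf2, encoding GM-CSF, had a gene-end peak in vehicle replicate 2 and lactate replicate 1 alone.

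For the Th17 genes, closeness to the detection limit stays open. At −log10 q of at least 2, 2 of 30 genes kept the pattern (Fisher's exact test, p = 0.0522). Their gene-end peaks in vehicle replicate 1 had −log10 q of 1.51 (Il17f), 1.36 (Ccl20), 2.69 (Ccr6), 2.67 (Il23r) and 1.85 (Il24). With the same number of peaks 5 genes had the pattern (Fisher's exact test, p = 0.000370). That setting keeps every peak of vehicle replicate 1, the shortest list, and cuts only the other lists. No gene could lose the pattern there, so this count cannot decide the question. A wrong label was not tested on these genes, and no biological explanation was tested.

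The match of the authors' deposited gained genes to peaks of vehicle replicate 2 and lactate replicate 1 is not a matter of the number of such peaks, which took in 8.94% of other coding genes. A candidate explanation is that the lists of vehicle replicate 2 and lactate replicate 2 changed places between the authors' gained analysis and the deposited files, which the share of 93.8% is consistent with. Which naming is right cannot be told apart here, since 3 splits give no p below 0.333. At the authors' threshold, similarity within minus across was 0.0063 for the split that puts vehicle 2 with lactate 1 and −0.00461 for that of the labels, with 2751 gained and 280 lost regions under the crossed naming against 2527 and 99. Of these, 216 gained and 25 lost regions lay at a gene end under the crossed naming, against 303 and 9 under the labels. At −log10 q of at least 5 the values ran the way of the labels, with 395 and 69 regions under the crossed naming against 2204 and 11 and a similarity difference of 0.0549 for the labels, but the share of peaks past that value (22.5% and 22.1% for vehicle, 31.2% and 30.8% for lactate) may also reflect depth.

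The excess of lactate-only regions at stricter thresholds may reflect depth. Peaks with a fold of 3.9 to 4.1 had a median −log10 p of 4.67 and 5.02 in the vehicle lists and 6.66 and 5.91 in the lactate lists, so the lowest lactate value exceeded the highest vehicle value by 0.890. With the same number of peaks the ratio of lactate-only regions to the highest other pair was 0.908. It was already 0.919 at the authors' threshold, so this setting cannot test the excess at stricter thresholds. Among the 10000 highest peaks of each list by −log10 p the ratio was 1.01. Regions brought by lactate stay open as an explanation, because fixing the number of peaks would also remove a general gain.

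Peaks on chromosome Y numbered 4 and 6 in the vehicle lists and 42 and 17 in the lactate lists, and peaks on unplaced sequence 4, 5, 29 and 9.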
